A study of Mus musculus with 5 samples.

How the data were processed

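RNA from 5 cultures of MLE-15 cells was hybridised to whole-transcript oligonucleotide arrays, 1 biotin-labelled sample per array. MLE-15 is a mouse lung epithelial line that came from tumours of transgenic mice in which the human surfactant protein C promoter drove the SV40 large tumour antigen. Per the labels' protocols, cells received a GFP-marked lentivirus that carried either an shRNA against Grhl2 or a non-targeting shRNA. Infection lasted 16 h at a multiplicity of infection of 50 with 5 µg/ml polybrene, and stable lines were selected with 5 µg/ml puromycin for 6 days. Labelling started from 300 ng of total RNA. The labels describe each of the 3 Grhl2 shRNA samples and the 2 non-silencing control samples as an independent transduction, and these transductions were the replicates. A single hairpin against Grhl2 is named.

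The authors deposited 1 table of log2 expression values, made with RMA in Affymetrix Expression Console per the submitters' processing notes. RMA corrects background, normalizes quantiles between arrays and summarises the probes of each probe set. Software versions, probe set annotation and any filters are not given in the sources used here. The log base was taken from the RMA method and from the range of the values, and no scanner files were used. The table's 34760 probe sets include 21640 that the platform annotation pairs with exactly 1 gene symbol, 1321 with several and 11799 with none listed. Probe sets with several symbols or none were not named. Of the single-symbol probe sets, 21553 were matched by Entrez ID to the RefSeq gene table of assembly GRCm38.p6, which changed no symbol, and 87 kept the annotation's symbol. Array positions are not given because the build of the values is not given in the sources used here.

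Single-symbol probe sets with a mean log2 value over the 5 arrays below 4.22, the 25th percentile, were left out, which kept 16230. Where a gene had several probe sets, the one with the highest mean stood for it, giving 14979 genes. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without a trend in the variance prior. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Values are log2 means ± SD per group, and differences are log2 fold changes (shRNA minus control) with the moderated standard error. With 3 residual degrees of freedom per gene, the number of arrays limits the precision. The median standard error of a log2 fold change was 0.051. For Grhl2, an exact two-sided permutation test over the 10 splits of the 5 arrays was added, which cannot give a p below 0.1.

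The 18 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 18 lists, then with a correlation estimated from the arrays, and with fry, whose directional p asks whether members move one way on balance. Counts "adjusted over the list alone" use Benjamini-Hochberg adjustment within that list. The genes named are Grhl2, Grhl1, Grhl3 and Nkx2-1, and the 12 largest rises and 12 largest falls among called genes whose groups did not overlap. From each list, called members were named up to 6 by size, or the 2 largest changes where fewer than 2 were called. Predicted genes, RIKEN clones, olfactory and vomeronasal receptors, microRNAs, small RNAs, antigen receptor segments and accession-named genes were left out of the ranking, and 30 such genes were called.

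The test was checked on simulated arrays with the real means of the 14979 genes, spreads drawn from the variance prior fitted to them, and 200 changed genes, in 10 runs. It recovered 21.0% of genes changed by a log2 value of 0.25, 89.6% of those changed by 0.5 and 99.7% of those changed by 1. Of its calls, 5.27% were false. Values were simulated independently with spreads from the test's own prior, so a false share near the threshold was built in. That share does not show how many calls were false in the real data. Recovery also depends on the number of changed genes, here 200 of 14979. In the real data, an estimated 69.4% of genes were unchanged. In simulated lists of 25 genes shifted by 0.1, camera called 20 of 20 with the preset correlation and 0 of 20 with an estimated one, with 0 calls in 180 unshifted lists under either. The simulated genes were drawn independently, so these lists cannot show false calls that come from correlation between genes. In the real lists the estimated correlation reached 0.25, for the interferon response. Alternatives covered the filter, the normalization, the choice of probe set, the variance prior, array weights, the replicate number as a block, each array left out, the threshold, all probe sets tested together and the list test. Removal of a trend with gene length, gene families defined by symbol and a comparison of X-linked with autosomal genes were added after the data were seen. A list of LXR targets was used in 1 test of the closing section.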

Results

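Gene expression was measured in MLE-15 mouse lung epithelial cells after lentiviral transduction with an shRNA against Grhl2, which encodes a Grainyhead-like transcription factor of epithelia, or with a non-silencing shRNA. The series set out to identify genes that depend on Grhl2 in lung epithelium. There were 3 Grhl2 shRNA arrays and 2 control arrays, each from its own transduction of the same cell line. Median log2 signal lay between 5.29 and 5.32 on every array. Over the genes tested, arrays of the same group correlated at r = 0.9984 to 0.9987 and arrays of different groups at 0.9967 to 0.9971, a correlation across genes, which are not independent replicates. The first principal component held 56.2% of the variance and separated the groups.

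Grhl2 itself (probe set 10423770) had log2 values of 7.43, 7.43 and 7.60 on the knockdown arrays and 7.77 and 7.68 on the control arrays. The knockdown mean was 7.49 ± 0.10 (SD, n = 3) and the control mean 7.72 ± 0.06 (SD, n = 2). The log2 fold change was −0.24 with a standard error of 0.065, which leaves 85.0% of the control signal, with a 95% confidence interval of 76.4 to 94.5%. All 3 knockdown values lay below both control values, but the limma adjusted p of 0.082 missed the threshold, and the exact two-sided permutation p was 0.2. The call depended on the arrays: without knockdown replicate 3, which had the highest Grhl2 value of its group, the limma adjusted p was 0.047. Without knockdown replicates 1 and 2 it was 0.170 and 0.201. The log2 fold change was −0.19 and −0.28 without control replicates 1 and 2. The paralogs Grhl1 (10394954) and Grhl3 (10517401) had log2 fold changes of −0.04 (adjusted p = 0.74) and −0.08 (adjusted p = 0.59). Nkx2-1 (10400474), a master regulator of lung epithelium, had means of 10.00 in both groups and a difference of −0.004, with a 95% confidence interval of −0.10 to 0.09.

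**Figure D1:**
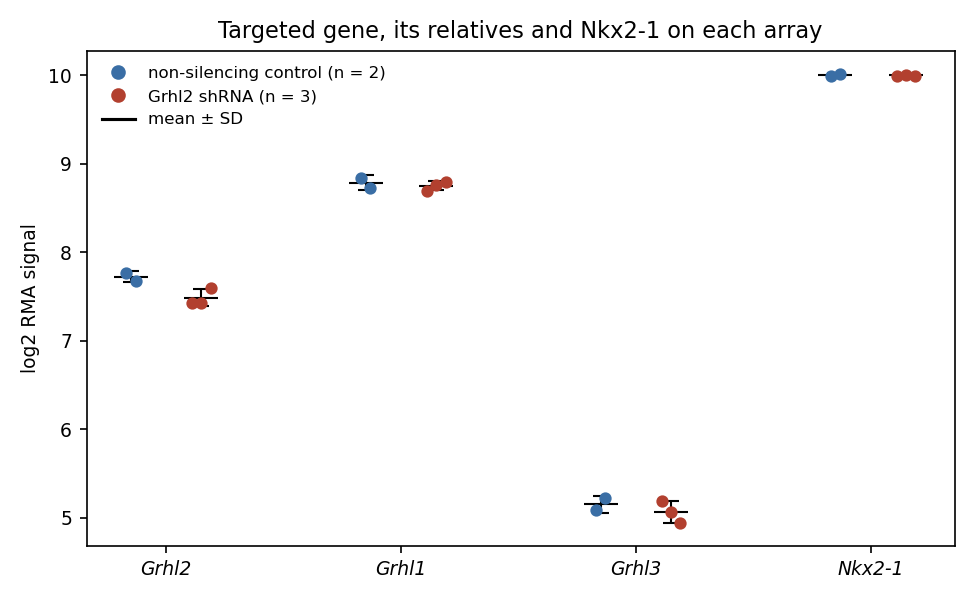
Log2 RMA signal (vertical axis) of Grhl2, Grhl1, Grhl3 and Nkx2-1 (horizontal axis) on each of the 2 control arrays and 3 Grhl2 shRNA arrays, with bars for mean ± SD. The Grhl2 values are 7.43 to 7.60 in the knockdown and 7.68 to 7.77 in the control, while the groups overlap for the other 3 genes.

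Across the genome, Fabp5, a fatty acid-binding protein, fell most, and Bex1, a small X-linked adaptor protein, rose most. Fabp5 (10585699) went from 8.18 ± 0.14 in the control to 6.55 ± 0.16 in the knockdown, 3.09-fold lower (log2 fold change −1.63, SE 0.10, adjusted p = 0.0017). Bex1 (10606868) went from 5.60 ± 0.17 to 7.12 ± 0.04, 2.87-fold higher (log2 fold change 1.52, SE 0.073, adjusted p = 0.0011). In all, 956 of 14979 genes passed the threshold, of which 429 were higher and 527 lower. Most changes were small: the median absolute log2 fold change among them was 0.28, a 1.22-fold change. Of the 956, 66 changed at least 1.5-fold (33 higher, 33 lower) and 10 at least 2-fold (5 higher, 5 lower). Several probe sets existed for 54 of the 956 genes, and for 6 genes they changed with opposite signs. Fabp5 had 2 probe sets, which changed with the same sign, and only the brighter is given. The groups did not overlap in any of the 956 genes, which mostly follows from the call itself with 3 against 2 arrays. Among all genes tested, the groups did not overlap in 41.5%, against 20% by chance. The count was 91 without control replicate 1 and 67 without control replicate 2, and 453, 289 and 493 without knockdown replicates 1, 2 and 3. It was 418 with no filter, 9 with no moderation of the variance and 2034 with a trended robust prior, and no probe set passed when all 34760 were tested together with limma, where 4515 had an unadjusted p under 0.05.

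Among the 12 largest rises, Scgb3a1 (10375608), an airway secretoglobin, rose by 1.23 on the log2 scale, and Stc1 (10416181), the glycoprotein hormone stanniocalcin, by 1.17. Tek (10505954), the angiopoietin receptor, rose by 0.91, Cd80 (10435704), a co-stimulatory ligand of T cells, by 0.86, and Abcg2 (10538640), a drug efflux transporter, by 0.85. The mast cell and basophil proteases Mcpt2 (10415438) and Mcpt8 (10420254) rose by 0.96 and 0.89. The glycosyltransferase B4galnt2 (10390196) was 2.14-fold higher, and Galntl5 (10520277) rose by 0.95, Hddc2 (10362394) by 1.30 and the interferon-inducible Ifi27 (10397975) by 0.91. Adjusted p-values of these 12 genes ran from 0.0011 to 0.011.

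Among the 12 largest falls, Fgb (10498981), the fibrinogen beta chain, fell by 1.40 and Hapln1 (10406519), a link protein of hyaluronan matrix, by 1.23. Xist (10606178), the RNA that silences an X chromosome, fell by 1.19, and the transcriptional repressor gene Klf12 (10422013) was 2.14-fold lower. Stra6 (10585803), a receptor for retinol uptake, fell by 0.87, the tight junction gene Cldn8 (10440647) by 0.91 and Ghrl (10546962), which encodes ghrelin, by 0.77. The other falls were R3hdml (10478383) by 1.00, Tnip3 (10538791) by 0.95, Tm4sf1 (10498273) by 0.82 and Smim31 (10578952) by 0.78. Their adjusted p-values ran from 0.0011 to 0.041. Of these 24 largest rises and falls, 14 stayed past the threshold whichever array was left out, and the other 10 were Stc1, Mcpt2, Galntl5, Tek, Xist, Klf12, Tnip3, Cldn8, Smim31 and Ghrl.

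**Figure D2:**
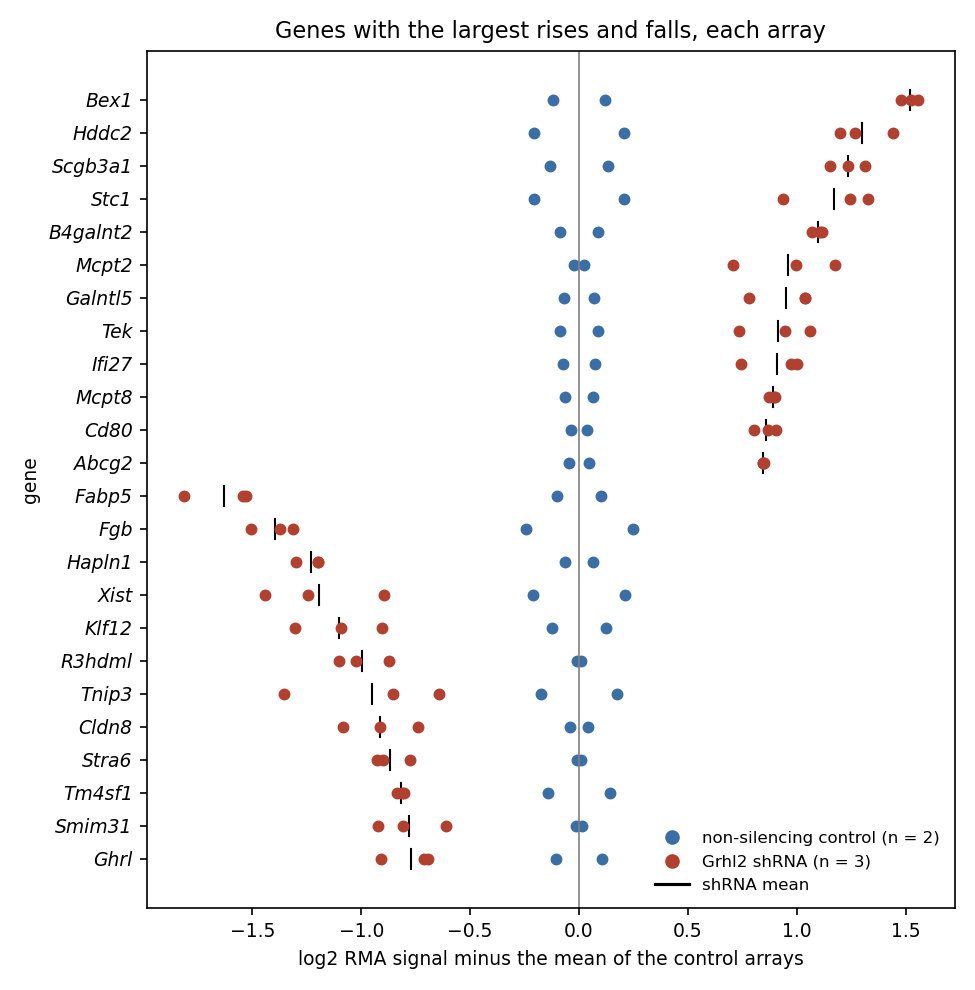
Log2 RMA signal of each array minus the mean of the control arrays (horizontal axis) for the 12 genes with the largest rises and the 12 with the largest falls (vertical axis), with a black line at the mean of the 3 Grhl2 shRNA arrays. By the rule that chose the 24 genes, the knockdown arrays lie apart from the control arrays for each of them, from Bex1 at 1.52 to Fabp5 at −1.63.

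The gene lists ask which functions of lung epithelium moved together. With the preset correlation, camera called 9 of 18 lists, 7 lower and 2 higher. With an estimated correlation it called 0, and the smallest adjusted p was 0.144. That setting also called 0 of 20 lists shifted by 0.1 in simulation. A missing call there therefore does not show that a list with so small a shift stayed unchanged. The simulation does not cover shifts as large as the interferon (0.24) and cholesterol (−0.21) medians given below. Its lists were also adjusted together with 180 unshifted ones, unlike the 18 real lists. The directional test of fry called 10 lists, among them the same 9.

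Junction genes fell slightly as groups. Of 27 tight junction and apical polarity genes, 1 rose, 3 fell and 23 did not pass the threshold; adjusted over the list alone, 2 were higher and 5 lower. Cldn8 fell by 0.91 (SE 0.094), Cldn4 (10534395), a claudin of tight epithelia, by 0.42 (SE 0.093), and Cgn (10500021), the junction scaffold cingulin, by 0.20, while Cldn12 (10527965) rose by 0.25. The list's median log2 fold change was −0.08, with a camera adjusted p of 0.0084 and an adjusted p = 0.192 with an estimated correlation. Of 23 adherens junction and desmosome genes, 20 had values below 0, but only Vcl (10413059), the actin linker vinculin, passed, and it fell by 0.38. Adjusted over the list alone, 4 were lower and 0 higher. Dsp (10404649), the desmosomal plaque gene desmoplakin, had a log2 fold change of −0.26 (adjusted p = 0.063), and Cdh1, E-cadherin, chosen after its value was seen, −0.07 (adjusted p = 0.32). The median was −0.07, with a camera adjusted p of 0.0015 and an adjusted p = 0.279 with an estimated correlation.

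Epithelial genes that work in other epithelia has linked to Grhl2 were also lower as a group. Of 26 tested, 4 fell, 0 rose and 22 did not pass; adjusted over the list alone, 6 were lower and 3 higher. The 4 were Cldn4, Cgn, Prss8 (10568332), the membrane protease prostasin, which fell by 0.21, and Esrp2 (10581455), an epithelial splicing regulator, which fell by 0.21. The list shares 6 tested genes with the tight junction list, including Cldn4 and Cgn. Its median was −0.07, with a camera adjusted p of 0.036 and an adjusted p = 0.370 with an estimated correlation. The call ended without knockdown replicate 1 (adjusted p = 0.082), knockdown replicate 2 (adjusted p = 0.051) or control replicate 1 (adjusted p = 0.111), with no filter (adjusted p = 0.063) and with the filter at the 50th percentile (adjusted p = 0.079). Of 21 keratin and epithelial cytoskeleton genes, Krt80 (10432682) fell by 0.32 and Epb41l5 (10357164), a regulator of the cortical cytoskeleton, by 0.24. None rose and 19 did not pass, and adjusted over the list alone the count was again 2 lower and 0 higher. The median was −0.05, with a camera adjusted p of 0.035 and an adjusted p = 0.197 with an estimated correlation. That call ended without knockdown replicate 1 (adjusted p = 0.051) or control replicate 2 (adjusted p = 0.123) and with the filter at the 50th percentile (adjusted p = 0.079).

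Markers of alveolar type I cells, the flat cells of gas exchange, were lower as a group. Of 18 tested, 7 fell, 0 rose and 11 did not pass; adjusted over the list alone, 8 were lower. The sodium channel subunits Scnn1a (10541885) and Scnn1g (10557111) fell by 0.57 (SE 0.090) and 0.37 (SE 0.067). Clic5 (10445347) fell by 0.51, and Ager (10444407), the receptor for advanced glycation end products, from 10.89 ± 0.04 to 10.40 ± 0.03. Ahnak (10461369) and Lmo7 (10416800) fell by 0.29 and 0.25. Of the 18, 14 had values below 0 and 4 above. Among the 11 that did not pass, Pdpn, Cav1, Aqp5 and Hopx were chosen after their values were seen. They were at −0.15, −0.07, −0.07 and 0.01 (limma adjusted p = 0.31, 0.56, 0.50 and 0.92). The median was −0.14, with a camera adjusted p of 3.3e-05 and an adjusted p = 0.144 with an estimated correlation. Alveolar type II genes, of the cell type the line models, went both ways: of 21 tested, 3 rose, 2 fell and 16 did not pass, with 4 higher and 3 lower adjusted over the list alone. Etv5 (10363901), a transcription factor of type II cells, rose by 0.43, Napsa (10552697), a protease that processes surfactant protein, by 0.36 and the chemokine Cxcl15 (10523145) by 0.27. Fabp5 fell by 1.63 and the surfactant protein gene Sftpd (10419096) by 0.33. Etv5, like Fabp5, had 2 probe sets that changed with the same sign, and only the brighter is given. The median (−0.004) and mean (−0.05) were below 0 while camera's direction was up (adjusted p = 0.72).

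The lists of airway genes, of endothelial and immune genes and of lung transcription factors did not pass the test. Of 20 airway genes, Scgb3a1 rose and 19 did not pass, among them Cyp2b10 (10551197) at 0.42 (adjusted p = 0.054). Adjusted over the list alone, 3 airway genes were higher and 1 lower, and the camera adjusted p was 0.22. Of 11 endothelial and immune genes, Tek rose by 0.91 and Tyrobp (10551883), a myeloid signalling adaptor, by 0.28 at a low signal of 4.61, and 9 did not pass. Adjusted over the list alone, 3 were higher. The list's median was −0.05 and its mean 0.08, with camera's direction up (adjusted p = 0.66). With the filter at the 50th percentile, which leaves fewer of these members, the median was 0.42 (camera adjusted p = 0.29). That value is not a shift of the same genes. Of 33 lung and epithelial transcription factors, 2 rose, 2 fell and 29 did not pass; adjusted over the list alone, 5 were higher and 6 lower. Ehf (10485445), an epithelial ETS factor, fell by 0.73 and Foxp2 (10536444), a forkhead factor of lung epithelium, by 0.27. Sox9 (10382328), a factor of the distal lung bud, rose by 0.44, as did Etv5 by 0.43. The camera adjusted p was 0.83.

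Mesenchymal genes did not pass the test as a list. Of 25 tested, 1 rose, 3 fell and 21 did not pass, with the same counts of 1 and 3 adjusted over the list alone. Tgfb2 (10360920), a growth factor ligand, fell by 0.68 and Cdh2 (10457644), N-cadherin, by 0.60. The matrix protein gene Sparc (10386058) fell by 0.19, and the integrin gene Itga5 (10433114) rose by 0.24. The median was 0.04 while the mean (−0.04) and camera's direction were down (adjusted p = 0.71).

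Guidance genes fell more often than they rose. Of 29 semaphorin, plexin and neuropilin genes, 8 fell, 1 rose and 20 did not pass; adjusted over the list alone, 12 were lower and 2 higher. The secreted ligands Sema3a (10519717) and Sema3c (10519886) fell by 0.54 (SE 0.043) and 0.45 (SE 0.056), and the transmembrane ligand Sema6d (10475544) by 0.37. Of the co-receptors, Nrp2 (10346843) fell by 0.28 and Nrp1 (10576639) rose by 0.32, and the receptor Plxnb1 (10589368) fell by 0.26. The median was −0.07, with a camera adjusted p of 0.0017 and an adjusted p = 0.144 with an estimated correlation. Its size depended on the arrays: without control replicate 1 the median was −0.036 (camera adjusted p = 0.0079). Of 33 integrin, laminin and basement membrane genes, 1 rose, 3 fell and 29 did not pass, with 3 higher and 9 lower adjusted over the list alone. Itgb6 (10483000), an epithelial integrin subunit, fell by 0.50, the collagen IV gene Col4a4 (10356088) by 0.30 and the dystroglycan gene Dag1 (10596893) by 0.23, while Itga5 rose by 0.24. The median was −0.05 and camera missed the threshold (adjusted p = 0.055, and adjusted p = 0.279 with an estimated correlation), whereas fry's directional adjusted p was 0.049.

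Planar cell polarity genes and genes of membrane traffic and membrane proteases did not pass as lists. Of 25 polarity genes, 24 did not pass and 1 fell, the Wnt receptor gene Fzd2, chosen after its value was seen, by 0.18. Fzd6 (10423825) and Wnt7b (10431210) had the largest values, 0.32 (adjusted p = 0.079) and 0.28 (adjusted p = 0.124). Adjusted over the list alone, 2 were lower, and the camera adjusted p was 0.48. Of 26 traffic and protease genes, Prss8 and Exph5 (10585331), an effector of Rab27 proteins, fell by 0.21 and 0.37 and 24 did not pass. Adjusted over the list alone, 2 were lower, and the camera adjusted p was 0.66.

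Interferon response genes were higher as a group. Of 29 tested, 12 rose, 1 fell and 16 did not pass; adjusted over the list alone, 22 were higher and 2 lower. Rtp4 (10434778) went from 6.22 ± 0.16 to 7.00 ± 0.17, 1.72-fold higher. Ifi27l2a (10402347) rose by 0.71 (SE 0.066), and the oligoadenylate synthetase family genes Oasl2 (10524621) and Oas1a (10533256) by 0.64 and 0.54. Irf7 (10569102), an interferon regulatory factor, rose by 0.55 and Xaf1 (10378068) by 0.58. The gene that fell was Ifit3, chosen after its value was seen, by 0.29. The median was 0.24, with a camera adjusted p of 4.2e-11 and an adjusted p = 0.197 with an estimated correlation.

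Cholesterol synthesis genes were lower as a group. All 19 tested members had a log2 fold change below 0, of which 8 passed and 11 did not, and adjusted over the list alone 15 were lower. Stard4 (10458033), a sterol carrier, fell by 0.46 (SE 0.097), and Hmgcs1 (10412466), the synthase at the start of the mevalonate pathway, by 0.35 (SE 0.044). The pathway enzymes Nsdhl (10600082), Tm7sf2 (10465342) and Fdps (10499483) fell by 0.31, 0.27 and 0.22, and Srebf2 (10425695), which encodes the sterol-regulated transcription factor of the pathway, by 0.26. The median was −0.21, with a camera adjusted p of 1.8e-09 and an adjusted p = 0.144 with an estimated correlation.

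Cell cycle genes were slightly higher as a group. Of 33 tested, 4 rose, 1 fell and 28 did not pass; adjusted over the list alone, 7 were higher and 2 lower. Cenpa (10520521), the centromeric histone, rose by 0.27, the spindle checkpoint kinase gene Bub1b (10474769) by 0.23, the replication factor gene Cdc45 (10438378) by 0.21 and the spindle motor gene Kif11 (10462796) by 0.20. Ccne1 (10562563), cyclin E1, fell by 0.35. The median was 0.09, with a camera adjusted p of 0.0021 and an adjusted p = 0.144 with an estimated correlation. Of 22 genes of the p53 and unfolded protein responses, Trib3 (10488608), a stress-induced pseudokinase, rose by 0.38, while Sdf2l1 (10438098), an endoplasmic reticulum chaperone cofactor, and Ccng1 (10385271), a p53 target, fell by 0.36 and 0.29. The other 19 did not pass, 5 were higher and 4 lower adjusted over the list alone, and the camera adjusted p was 0.72.

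**Figure D3:**
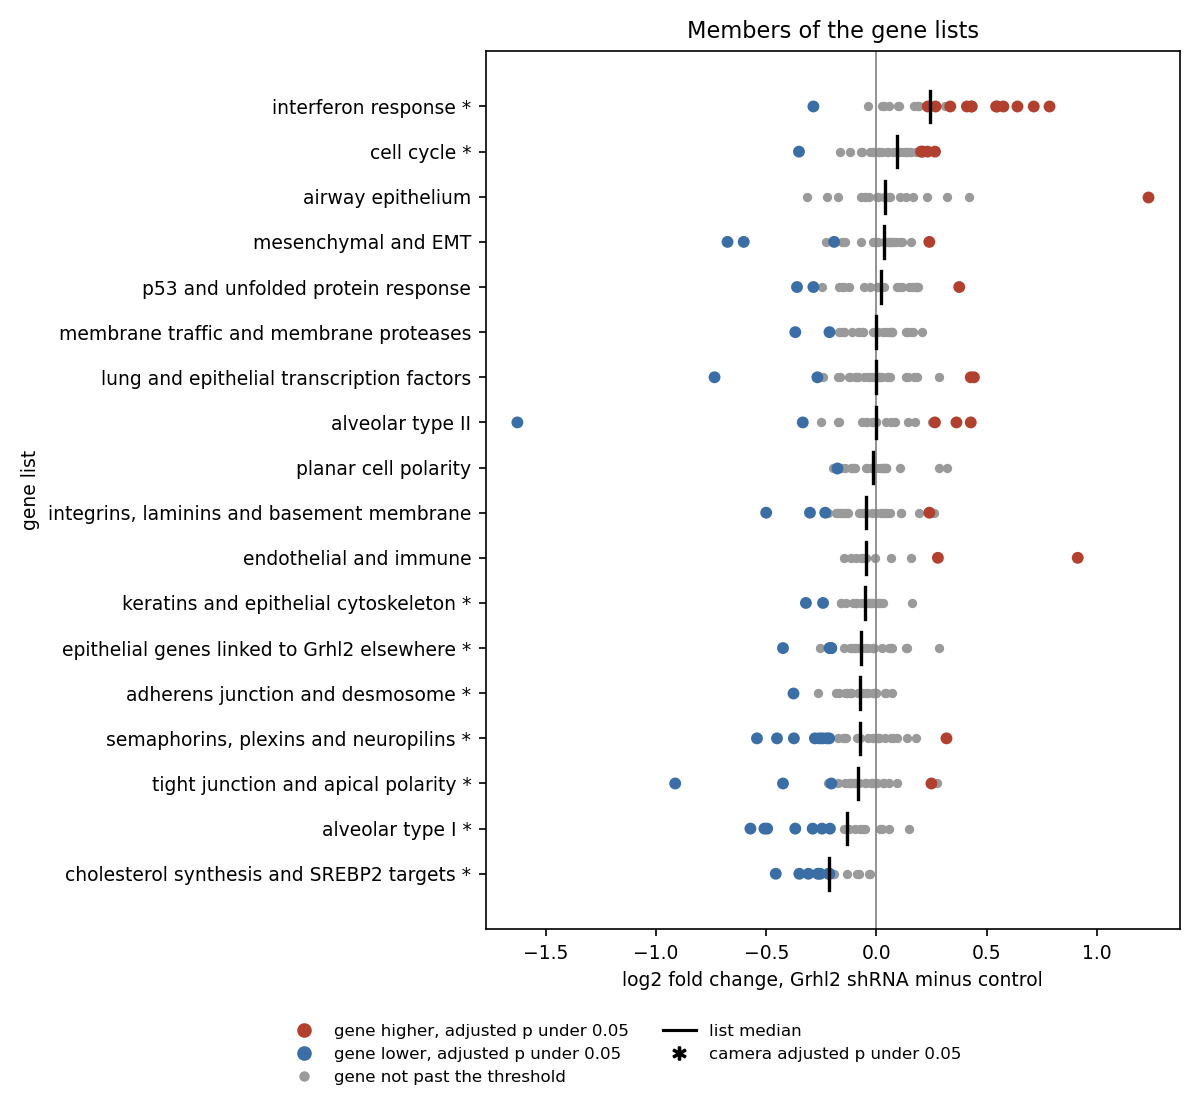
Log2 fold change of each tested member (horizontal axis, Grhl2 shRNA minus control) of the 18 gene lists (vertical axis), in colour where the gene's adjusted p was under 0.05, with a black line at each list's median and a star where camera's adjusted p with the preset correlation was under 0.05. Medians run from −0.21 for cholesterol synthesis to 0.24 for the interferon response.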

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

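Removal of a trend with gene length was chosen only after the data were seen. The number of genes past the threshold, 956 as reported, rested on the variance prior, the filter and the number of arrays. It was 418 with no filter on the mean, 1708 with the filter at the 50th percentile, 2034 with a trended robust prior, 9 with no moderation, 66 with a 1.5-fold minimum, 1851 at an adjusted p under 0.10, 3456 at an unadjusted p under 0.05 and 69 at that p with a 1.5-fold minimum. Testing all probe sets together gave 0 with limma, with 4515 at an unadjusted p under 0.05. With 1 array left out, the count ran from 67 to 493. Fits without a control array leave 1 control, which is assumed to vary like the knockdown arrays. The count was 937 to 1094 with the mean of probe sets, cyclic loess, median centring, array weights or the length trend removed. The 956 genes kept their sign in each of the fits that tested them, except 1 gene with the mean of probe sets. For most fits this was fixed in advance, also for the named genes among them. Since the groups did not overlap in these genes, no left-out array, array weight or replicate block could reverse a sign. The variance prior and the filter leave the fold change unchanged. Of 80 called named genes, none changed sign, 55 and 54 lost the call without control replicates 1 and 2, and 78 with no moderation. Beyond the fewer arrays or genes of some settings, the cause was not tested.

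The Grhl2 log2 fold change of −0.24 passed with the trended robust prior (−0.24, adjusted p = 0.023), with the 50th percentile filter (−0.24, adjusted p = 0.032) and without knockdown replicate 3 (−0.29, adjusted p = 0.047). With 1 array left out, it ran from −0.29 to −0.19. Over all settings its adjusted p ran from 0.023 to 0.320.

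With an estimated correlation, camera called 0 of 18 lists instead of 9. The list of integrins, laminins and basement membrane gained a call with cyclic loess (median −0.052, adjusted p = 0.0498), fry (−0.048, adjusted p = 0.049) and without control replicate 2 (−0.050, adjusted p = 0.027). An estimated correlation leaves the medians of the 9 lists as they were. They were −0.074 for adherens junction, −0.14 for alveolar type I, 0.093 for cell cycle and −0.21 for cholesterol synthesis. The Grhl2-linked list was at −0.072, interferon at 0.24, keratins at −0.052, semaphorins at −0.074 and tight junction at −0.082. The Grhl2-linked list also lost its call with no filter (−0.071, adjusted p = 0.063) and the 50th percentile filter (−0.071, adjusted p = 0.079), as did keratins with the latter (−0.062, adjusted p = 0.079). Calls held but medians moved for semaphorins without control replicate 1 (−0.036), with the mean of probe sets (−0.038) and with the 50th percentile filter (−0.16), and for alveolar type I with that filter (−0.23). With 1 array left out, the Grhl2-linked median ran from −0.078 to −0.052 and the keratin median from −0.067 to −0.049.

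Apart from that 1 gene, directions reversed only where nothing had passed. The test's direction changed for alveolar type II with the 50th percentile filter (median −0.022) and the replicate block (−0.0035), and for lung transcription factors with fry (−0.0043) and the 50th percentile filter (−0.000585). With 1 array left out, it changed in at least 1 fit for endothelial and immune genes (medians −0.077 to 0.026), lung transcription factors (−0.011 to −0.0035) and the p53 list (−0.011 to 0.075). Nkx2-1 was at 0.0049 with median centring and −0.018 to 0.0099 with 1 array left out, and Grhl1 at −0.095 to 0.022.

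Replicate numbers were not taken as pairing, since only replicates 1 and 2 exist in both groups and deviations of same-numbered arrays correlated at 0.057 and 0.019 across genes. With the replicate block, 172 genes passed and 9 lists were called.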

Other observations

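Gene families were tested by their shared symbol stem only after the data were seen, so their values are descriptions. A stem is the letters that start a symbol, so a family can also hold genes that are not ribosomal proteins. Of 31 genes with the stem Rps, used for ribosomal proteins of the small subunit, 4 rose and 0 fell. Their median log2 fold change was 0.11, and Rps21 rose by 0.34. The 35 genes with the stem Rpl, used for proteins of the large subunit, had a median of 0.10, with 3 called higher. Of the mitochondrial ribosomal genes, 3 of 29 Mrps genes (median 0.10) and 4 of 48 Mrpl genes (median 0.08) rose, among them Mrps6 by 0.50. Box C/D small nucleolar RNAs, which guide ribosomal RNA methylation and mostly lie in introns of host genes, had a median of 0.13 over 28 Snord genes, of which 7 rose, among them Snord42a by 0.63 and Snord15b by 0.42. Of 12 genes with the stem Lrp, 2 fell, Lrp1 by 0.34 and Lrp8 by 0.23, and the median was −0.11. Camera with the preset correlation called 15 of 249 families, and 0 with an estimated correlation (adjusted p = 0.89 for each of the 15). Ribosomal protein genes have many near-identical pseudogenes, so a probe set can take signal from several copies.

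Fold changes had little trend with gene length, taken as genomic span for 14933 genes (Spearman's rho −0.046 across genes, which are not independent replicates). After that trend was removed from each array, 13 of the 15 families kept their call, and the exceptions were Mrpl (median 0.081 before and 0.079 after, adjusted p = 0.060) and Snora (0.175 and 0.141, adjusted p = 0.25), whose medians stayed above 0. Genes on the X chromosome of assembly GRCm38.p6 had a median log2 fold change of −0.018 over 390 genes, against 0.003 for 14541 autosomal genes, with 11 called higher and 26 lower, beside the fall of Xist. The difference is small, and its permutation p of 0.00054 shuffles genes, which are not independent replicates. Probe sets with several symbols or none held no call with limma: 0 of 991 and 0 of 8849 passed, with 164 and 683 at an unadjusted p under 0.05.

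The tests of splits, of single arrays, of signal level and of the number of hairpins below were chosen only after the result was seen. Many genes passed while the Grhl2 probe set moved little. The design has 1 hairpin against Grhl2. Effects of that hairpin on other genes therefore cannot be told apart from effects of Grhl2 loss, for any gene or list here. For copy number differences between the lines, a median of 0.2 over runs of 51 neighbouring genes was set in advance. The largest absolute median was 0.086, which argues against a shared shift of 0.2 over any such run. It was above the 0.073 of the shuffled orders' 95th percentile, as were 7 of 13949 overlapping runs. In the largest run 14 of 51 genes were called, against 956 of 14979 among all genes tested. Smaller regional differences in copy number therefore stay open. The 10 splits of the 5 arrays into 3 and 2 are too few for a share under 0.05: the labelled split called 956 genes, the highest other 0, and 1 split called as many as the labelled one, itself. Whether the remaining Grhl2 level sets the size of the response cannot be told apart from array differences: knockdown replicate 3, with the highest Grhl2 value, had a slope of 0.866 on genes changed in the other arrays, against 0.893 and 0.981, and the gap of more than 0.1 set in advance for both was met only for the latter.

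Of 29 interferon response genes, 12 rose, 1 fell and 16 did not pass, with a camera adjusted p of 4.2e-11 and an adjusted p = 0.197 with an estimated correlation. A single array as the cause is argued against by the smallest of the 3 knockdown arrays' median shifts, 0.16, and a bias with signal level by 0% of 10000 signal-matched lists that reached the list's median. A response to the hairpin rather than to the loss of Grhl2 cannot be told apart from a Grhl2 effect, because the design has 1 hairpin against Grhl2. The hypothesis that this hairpin may have raised these genes therefore stays open, beside a biological effect of the knockdown.

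Of 19 cholesterol synthesis genes, 8 fell and 11 did not pass, with a camera adjusted p of 1.8e-09 and an adjusted p = 0.144 with an estimated correlation. A single array is argued against by the smallest of the 3 knockdown arrays' median shifts, −0.18, and a bias with signal level by 0% of 10000 signal-matched lists that reached the median. A higher sterol level in the knockdown cells is a candidate explanation that would also raise LXR targets, the genes that sterols induce. The median of 9 LXR targets was −0.005, at percentile 42.49 of signal-matched lists, with members on both sides of 0. The rule set in advance counted a median below the 50th percentile against this explanation, and the value met that rule. A further condition, that the gap exceed the median's spread, was added after the value was seen. The gap was smaller than that spread, so the value is taken to decide nothing. A biological effect of Grhl2 loss and an effect of the hairpin both stay open.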
